A study of Mus musculus with 8 samples.

How the data were processed

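Sperm small RNA of 8 mouse samples was compared between 4 control and 4 ethanol samples, with groups and replicate numbers taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with Qiaseq reagents. Such kits can add molecular identifiers, but whether the deposited values count reads or molecules is not given in the sources used here, and neither are the aligner, the counting rule and the genome build. The authors deposited 1 table of whole-number counts per annotated feature and library, per the file headers for miRNAs, hairpins, exons, introns, sense and antisense transposons, structural RNAs and piRNA clusters. No normalization is recorded, and library totals ran from 3481865 to 6975180 counts. As the build is unknown, no coordinates are given, and names are those of the table, which names tRNAs by codon.

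The table had 1078961 rows. Of 783825 transposon rows 149699 were 0 in every library, and how reads with several alignments were placed is not given in the sources used here, so rows with the same name and type were summed. Transcripts of a piRNA cluster carried the same counts as another transcript of that cluster in 144 of 339 cases, so each of 172 clusters was represented by its largest transcript. Exons were divided by transcript type into mRNA exons, noncoding exons, snoRNAs and mitochondrial genes, and structural RNAs into their annotated classes, which gave 45090 features in 16 classes. The 278 exon rows that name more than 1 gene were kept under their joint name. Near-identical gene copies, overlapping genes and antisense genes are uncertain, since the counting could divide or share their reads.

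Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group with its minimum count of 10, robust quasi-likelihood fit with group as the only term, Benjamini-Hochberg adjustment, threshold 0.05). CPM, counts scaled to a common library size, used TMM factors. The standard error of a log2 fold change is its absolute value divided by the square root of the F statistic. Values are given as mean ± SD over 4 libraries, and log2 fold changes of ethanol against control as estimate ± SE. Shares of the 16 classes, as percent of the summed deposited counts, were compared by a two-sided exact permutation test over 70 assignments and adjusted over classes. Gene lists were tested with camera on log2 CPM with a preset inter-gene correlation of 0.01, again with the correlation estimated, and with fry in limma 3.58.1, with adjustment over lists; lists with under 3 tested members got no set test. Shares, intervals and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

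The lists were the let-7 family, the miR-34 and miR-449 family, the miR-30 family, the family of miR-10, miR-99, miR-100 and miR-125, the X-linked testis cluster, the miR-17-92 and paralogous clusters, miRNAs linked to paternal stress or alcohol, and miRNAs of oxidative stress, hypoxia and mitochondria. Others held miRNAs of epithelium, red blood cells, white blood cells, muscle and stroma, and liver. The rest held tRNAs with abundant fragments in mature sperm, mitochondrial tRNAs and rRNAs, mitochondrial protein-coding genes, nuclear oxidative phosphorylation genes, Y RNAs, and transcripts of spermatids and sperm, of epididymal epithelium and of blood and immune cells. Features named in the text followed a rule: the 12 with the smallest p in each direction, the 5 miRNAs with the smallest p in each direction, in each list up to 4 members past the threshold or otherwise the 2 with the highest mean CPM, and the 2 features of each class with the highest mean CPM. Other named features are said to have been chosen after their values were seen.

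The fit was tested on simulated counts of 13515 features drawn from the means and library sizes of the ethanol against control comparison. Of 100 features changed 2-fold 1% were recovered and of 100 changed 4-fold 48%, with 4 false calls among 53. Few features were changed there, so the adjustment was stricter than in the real comparison. These percentages therefore do not give the power of the real comparison. Chi-square statistics per degree of freedom between libraries of a group were 9.22 to 122, so no pair of libraries agreed within sampling noise and all were kept as replicates. Of 124 miRNAs with a median above 100 counts 23 were at 0 in at least 1 library, against 5 of 1627 features of other types, so a 0 of an abundant miRNA is given only as listed at 0.

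Alternatives were DESeq2 size factors, library totals, the DESeq2 1.42.0 Wald test, limma-voom, other count filters, the replicate number as a block, each library left out, each pair of ethanol libraries whose sample codes share a style, and miRNAs or tRNAs alone in the fit. For shares they were a log2 scale, the total without rRNA, centred log-ratios and sign flips over replicate numbers. Added after seeing the data were the largest row per name in place of the sum, miRNAs with a doubtful 0 left out, and both replicates numbered 2 left out. Read counts in place of molecule counts were not compared, since the table gives 1 value per library.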

Results

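Small RNA was sequenced from mouse sperm in a series on sperm noncoding RNA after alcohol exposure had ended, and the design compares control with ethanol treatment. The labels describe 8 libraries, 4 control and 4 ethanol, made from total RNA with Trizol and Qiaseq reagents. The deposited table held 4529439, 4365887, 4503011 and 4921827 counts for control replicates 1 to 4, and 6849448, 3481865, 6975180 and 5948251 for ethanol replicates 1 to 4. After rows with one name were summed, 45090 features of 16 RNA classes remained, and 13515 had enough counts to be tested. The labels do not say that the samples of a group came from separate animals, so the p-values measure only the spread between these samples. Ethanol replicate 2 stood apart: across features its log2 CPM correlated with those of the other ethanol libraries at 0.686 to 0.820, against 0.903 to 0.936 between control libraries. Features are not independent replicates, and these correlations only describe the libraries.

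The comparison asks which small RNAs differ between sperm of the ethanol and control groups after cessation. miRNAs, short regulators of mRNA stability and translation, took 20.8% ± 4.84 of counts in control sperm and 8.69% ± 2.30 in ethanol sperm (SD, n = 4 each). Fragments of mRNA exons took 5.87% ± 0.271 in control and 14.4% ± 10.7 in ethanol sperm, and the small cytoplasmic Y RNAs took 0.0409% ± 0.00317 and 0.121% ± 0.0898. In these 3 classes every ethanol library lay on the same side of every control library, which gives the smallest two-sided p that an exact permutation test over 70 assignments can reach (p = 0.0286). Adjusted over 16 classes this became 0.152, so no class passed; at least 10 classes would have had to reach that smallest p for any to pass. tRNA fragments were the most abundant class by summed counts, with 35.01% ± 2.29 in control and 38.9% ± 11.5 in ethanol sperm. That difference was smaller than the spread between ethanol libraries (exact permutation p = 0.771), and its sign turned without ethanol replicate 4. Copies of a tRNA may carry the same counts: the largest of 3 rows of tRNA-Ser-TCA(m) held 33.3% of its counts in each group. Summed copies could then hold the same reads more than once. The tRNA share and its rank are therefore uncertain, and the other shares depend on them through the total. piRNA clusters, the loci of transposon-silencing RNAs in male germ cells, took 14.9% ± 3.47 and 15.7% ± 8.15 (exact permutation p = 0.857), and the sign of that difference turned without control replicate 2 or ethanol replicate 1 or 3. Ethanol replicate 2 alone had 30.4% mRNA exon counts (95% Wilson interval 30.4 to 30.5), and without it the difference in that share between group means went from 8.58 to 3.25 percentage points. The Y RNA difference went from 0.0804 to 0.0363 percentage points without that library. Intervals cover counting error only, and without any 1 control the exact permutation p was 0.114 for mRNA exons and 0.0857 for Y RNAs.

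**Figure D1:**
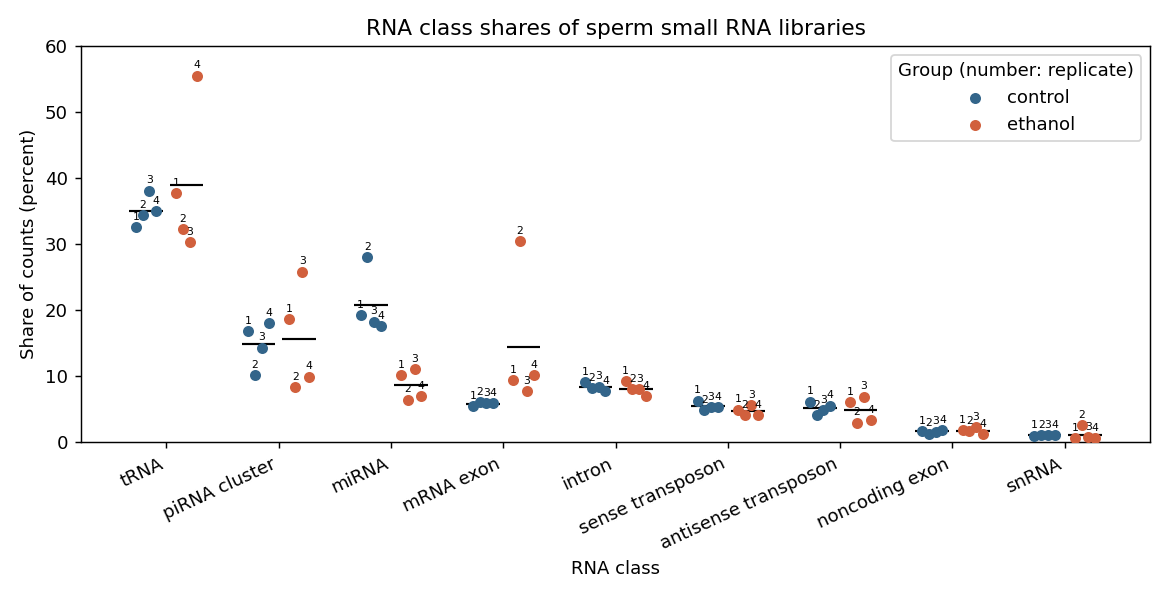
Percent of counts per library (y axis) in the 9 RNA classes that held at least 1% on average (x axis), for 4 control and 4 ethanol sperm libraries; points are libraries with their replicate number and bars are group means. Every ethanol library lies below every control library for miRNA, and ethanol replicate 2 stands at 30.4% for mRNA exons.

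Across all features, 1841 of 13515 changed in ethanol sperm (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 1604 upward and 237 downward. The classes moved apart. Of 6545 mRNA exon features 1560 rose and 10 fell, with a median log2 fold change of 0.88, while of 226 miRNAs 1 rose and 89 fell, with a median of -1.52. Of 5159 introns 13 rose and 97 fell, and of 89 snoRNAs, which guide modification of ribosomal RNA, 18 fell and 0 rose. With adjustment over each class alone 0 introns rose and 6 fell, while 23 snoRNAs fell and 0 rose. Of 38 miRNA hairpins 1 rose, that of mmu-mir-196a-1, and 9 fell, and of 182 noncoding exons 25 rose and 1 fell, Rmrp. Of 524 sense transposon features 3 rose, MuLV-int, RLTR3_Mm and RLTR4_Mm, and 7 fell. Of 552 antisense transposon features 1 rose, MMERGLN-int, and 4 fell, RLTR51B_Mm, MER45A, ERVB4_1-I_MM-int and ERVB5_1-I_MM-int, but none passed with adjustment over antisense transposons alone. Rmrp and these 8 transposons were named after their values were seen. The split depended on scaling: when libraries were scaled by their totals, 1602 features rose and 101 fell, with 16 introns up and 19 down, 4 sense transposon features up and 3 down, 1 antisense transposon feature up and 2 down, and 0 snoRNAs up and 4 down. Most calls of lower introns and snoRNAs were lost with that scaling. The count rests on every control library: without control replicate 1, 2, 3 or 4 it was 3, 3, 7 or 10, and the median adjusted p of the 1841 features was then 0.113, 0.0723, 0.0826 or 0.0677. In each class and list at most 10 features therefore passed without 1 of the controls. Without ethanol replicate 3 the count was 3575, without ethanol replicate 4 it was 1044, and limma-voom called 8. All 1841 features kept their sign without each control and with limma-voom. This was likely in advance, since the features were called in the same libraries, and it says little about stability.

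The rise with the smallest p was that of a feature annotated as miRNA under the precursor name mmu-mir-196a-1, whose gene lies in a Hox gene cluster, from 0.131 ± 0.152 CPM in control to 8.51 ± 4.26 CPM in ethanol sperm (SD, n = 4; log2 fold change 5.80 ± 0.73 SE, edgeR adjusted p = 0.0112). All 4 ethanol libraries lay above every control library, on 2 counts in control and 201 in ethanol sperm, a CPM ratio of 67.8 (95% exact binomial interval 18.5 to 564, counting error only). The mature arm mmu-miR-196a-5p, named after its value was seen, did not rise with it (log2 fold change -0.98 ± 1.67, edgeR adjusted p = 0.712). It was listed at 0 in control replicates 2 and 4 and ethanol replicate 1, and had 46.1 and 34.2 CPM in the other controls and 7.40, 25.8 and 7.61 CPM in ethanol replicates 2, 3 and 4. Its values therefore do not show a rise of the mature miRNA. The hairpin of mmu-mir-196a-1, counted as a separate feature, rose by 3.77 ± 0.68. The other 10 of the 12 rising features with the smallest p were mRNA exons, each higher in 4 of 4 ethanol libraries than in any control library. The calcium-binding protein genes S100a11 and S100a16 rose by 2.88 ± 0.50 and 2.98 ± 0.54, the former from 2.57 ± 0.595 to 19.1 ± 13.6 CPM. AI661453 rose by 3.41 ± 0.51, the peroxisome assembly gene Pex19 by 2.42 ± 0.42, the proton pump subunit gene Atp6v0e by 2.37 ± 0.42 and the tight junction gene Tjp3 by 2.59 ± 0.46. The centromere protein gene Cenpb rose by 2.43 ± 0.44, Tmod3, which caps actin filaments, by 2.23 ± 0.41, Babam1 by 2.88 ± 0.53 and Sh3bgrl3 by 2.80 ± 0.52. The edgeR adjusted p of AI661453 was 0.0221 and that of the hairpin and the other exons 0.0287. mmu-mir-196a-1 kept its call without each library in turn. The other calls ended without control replicate 1, 2 or 3, and all of these but AI661453 and the hairpin also without control replicate 4 (edgeR adjusted p 0.0514 to 0.0949).

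Sense-strand counts of the L1 element L1ME3A fell from 75.4 ± 27.9 to 5.74 ± 2.65 CPM (log2 fold change -3.70 ± 0.50, edgeR adjusted p = 0.0132) and those of the DNA transposon FordPrefect from 4184 ± 896 to 530.2 ± 271 CPM (-2.98 ± 0.50, edgeR adjusted p = 0.0287). A single annotated copy held 99.9% of the FordPrefect counts, so that value describes 1 locus. Of 150 annotated copies of L1ME3A 1 held 90.3% of the control counts, with 163 to 387 per library, and 7.97% of the ethanol counts, with 1 to 5, so the fall was that of this copy and most ethanol counts were of other copies. Introns of Gpc5, Hs1bp3, Trim67 and Fam20c fell, with log2 fold changes of -5.11 ± 0.85, -3.78 ± 0.55, -4.62 ± 0.76 and -4.10 ± 0.70, and 1 intron of each gene held 97.9%, 81.2%, 93.1% and 93.2% of the control counts but 53.6%, 6.25%, 0% and 12.5% of the ethanol counts. Gpc5 counts differed widely between controls, from 104.7 CPM in replicate 4 to 1150.1 in replicate 1. Introns of Rpl10 and Rbmx, which host snoRNAs, fell with log2 fold changes of -2.15 ± 0.37 and -2.27 ± 0.40. The snoRNA Snord32a fell from 65.5 ± 9.66 to 19.1 ± 5.02 CPM (-1.78 ± 0.37, edgeR adjusted p = 0.0287). Each of these features was lower in 4 of 4 ethanol libraries than in any control library. L1ME3A and Hs1bp3 kept their calls without each library in turn. Those of Gpc5, Trim67 and Fam20c ended without control replicate 1 or 2, and those of FordPrefect, Rpl10, Rbmx and Snord32a without control replicate 1, 2, 3 or 4 (edgeR adjusted p 0.0514 to 0.0949). Reads of an intron cannot be told apart from those of a snoRNA or antisense transcript inside it.

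Most miRNAs were lower in ethanol sperm. Of 226 tested, 205 had a negative log2 fold change; 89 fell and 1 rose over all features tested, and 127 fell and 2 rose with adjustment over miRNAs alone, the latter being mmu-mir-196a-1 and mmu-mir-7222 (named after its value was seen). When libraries were scaled by their totals, 61 fell and 1 rose. mmu-miR-16-5p, an abundant miRNA that represses cell cycle genes, fell from 65002 ± 15341 to 22953 ± 9781 CPM (-1.50 ± 0.47, edgeR adjusted p = 0.0475). The falls with the smallest p were those of mmu-miR-499-5p (-2.63 ± 0.51), mmu-miR-181a-5p (-2.63 ± 0.52), mmu-miR-669a-5p (-2.34 ± 0.47), mmu-miR-144-5p (-3.04 ± 0.68) and mmu-miR-743a-3p (-2.11 ± 0.48), all with an edgeR adjusted p of 0.0287. Each was lower in 4 of 4 ethanol libraries than in any control library. With miRNAs alone in the fit, which compares them with each other, the median log2 fold change was -0.10 and only mmu-mir-196a-1 passed, while mmu-miR-196a-5p had a log2 fold change of 0.04 ± 1.86 (edgeR adjusted p = 0.996). The count of 90 miRNAs went to 1 without control replicate 1, 2, 3 or 4, to 158 without ethanol replicate 3 and to 35 without ethanol replicate 4. The calls of the falling miRNAs named here ended without each control, that of mmu-miR-144-5p also without ethanol replicate 2, and that of mmu-miR-16-5p also without ethanol replicate 1 or 4 (edgeR adjusted p 0.0572 to 0.143). mmu-let-7a-5p was listed at 0 in control replicate 2 and had 64888 to 71185 counts in the other controls, so no group mean is given for it.

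The miRNA lists were fixed by family or cell type before the data were examined. Their counts and medians include members listed at 0 in some libraries, which may have kept those members from passing. Such were mmu-let-7a-5p and mmu-let-7c-5p in control replicate 2, mmu-miR-30a-5p and mmu-miR-142a-5p in 3 libraries and mmu-miR-141-3p in 4. All but mmu-let-7a-5p were named after their values were seen. With miRNAs with a doubtful 0 left out, 14 gene lists passed camera with the preset correlation, as with them. Of the X-linked testis cluster, expressed in male germ cells, 14 of 20 members fell (18 adjusted over the list alone), with a median log2 fold change of -1.75. mmu-miR-743a-3p fell from 1024 ± 289 to 237 ± 90.8 CPM, and mmu-miR-743b-3p (-2.05 ± 0.49), mmu-miR-465a-5p (-2.04 ± 0.48) and mmu-miR-881-3p (-2.21 ± 0.52) fell with it. Of the let-7 family, which promotes differentiation, 5 of 11 fell (8 adjusted over the list alone), with a median of -1.45. Among them were mmu-let-7b-5p (-1.76 ± 0.48), mmu-let-7e-5p (-2.44 ± 0.66), mmu-let-7i-5p (-2.22 ± 0.65) and mmu-miR-98-5p (-1.96 ± 0.55). Of the miR-17-92 and paralogous clusters, which promote proliferation, 7 of 10 fell (9 adjusted over the list alone), with a median of -1.58, among them mmu-miR-93-5p (-1.58 ± 0.44), mmu-miR-92a-3p (-1.59 ± 0.46), mmu-miR-17-3p (-2.01 ± 0.48) and mmu-miR-17-5p (-1.37 ± 0.41). Of the miR-34 and miR-449 family, which acts in male germ cell development, 1 of 6 fell (1 adjusted over the list alone), mmu-miR-34c-3p (-1.71 ± 0.45), and the median was -0.99. Of the miR-10, miR-99, miR-100 and miR-125 family 4 of 9 fell (5 adjusted over the list alone), with a median of -1.22. These were mmu-miR-125a-5p (-2.40 ± 0.59), mmu-miR-99b-5p (-2.40 ± 0.60), mmu-miR-100-5p (-2.19 ± 0.55) and mmu-miR-125b-5p (-1.51 ± 0.45). As sets against all other features these 5 lists passed camera with a preset correlation (adjusted p = 8.99e-12, 0.000135, 1.69e-06, 0.0316 and 0.000135 in the order given). None passed when the correlation was estimated: adjusted p = 0.218 with an estimated correlation for the miR-34 and miR-449 family and adjusted p = 0.210 with an estimated correlation for the other 4. The rotation test fry, which asks whether the members of a list moved one way and compares them with no other features, gave the 5 lists an adjusted p of 0.0375, 0.0375, 0.0314, 0.0798 and 0.0470. Over all lists 9 of 18 passed fry, but 0 without control replicate 4 or ethanol replicate 1. The call of the miR-34 and miR-449 family was also lost without control replicate 3 or 4 or ethanol replicate 1 or 4 (camera adjusted p = 0.0714, 0.0661, 0.05003 and 0.0939), and its median was -1.59 without ethanol replicate 3. Compared with other miRNAs alone, the medians of these 5 lists were -0.45, -0.06, -0.22, 0.29 and 0.29 in the same order, so the direction of the last 2 turned; only the X-linked cluster passed there (camera adjusted p = 0.0340 with the preset correlation; adjusted p = 0.646 with an estimated correlation). Without control replicate 2 the log2 fold changes of mmu-let-7e-5p, mmu-let-7i-5p, mmu-miR-99b-5p and mmu-miR-100-5p were -1.08, -1.21, -1.36 and -1.34. Each call on a single miRNA named here ended without each control. Those of mmu-let-7e-5p, mmu-let-7i-5p, mmu-miR-98-5p, mmu-miR-99b-5p and mmu-miR-100-5p also ended without ethanol replicate 2 or 4, those of mmu-let-7b-5p and mmu-miR-93-5p without ethanol replicate 4, and those of mmu-miR-92a-3p, mmu-miR-17-5p and mmu-miR-125b-5p without ethanol replicate 1 or 4 (edgeR adjusted p 0.0502 to 0.185).

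Of 10 tested sperm miRNAs linked to paternal stress or alcohol in earlier mouse work, 3 fell (5 adjusted over the list alone), with a median log2 fold change of -1.42, or -2.07 without ethanol replicate 3. They were mmu-miR-532-5p (-1.99 ± 0.49), mmu-miR-32-5p (-1.83 ± 0.58) and mmu-miR-30c-5p, which went from 5643 ± 768 to 1963 ± 773 CPM (-1.52 ± 0.44). Of 6 miRNAs of oxidative stress, hypoxia and mitochondria, 3 fell (6 adjusted over the list alone), with a median of -1.71, or -1.12 without ethanol replicate 4. These were mmu-miR-499-5p, mmu-miR-181a-5p and mmu-miR-181b-5p (-2.12 ± 0.60). Both lists passed camera with the preset correlation (adjusted p = 0.000570 and 0.000135) and neither when it was estimated (adjusted p = 0.210 with an estimated correlation for both); fry gave 0.0524 and 0.0314. Of the miR-30 family 1 of 7 fell (1 adjusted over the list alone), again mmu-miR-30c-5p. The family as a set did not pass (median -1.05, camera adjusted p = 0.207), but passed without control replicate 4 (0.0274). Compared with other miRNAs alone, the medians of the stress and alcohol, the hypoxia and the miR-30 lists were -0.11, 0.23 and 0.40, and none passed camera. The calls named here ended without each control, those of mmu-miR-30c-5p and mmu-miR-32-5p also without ethanol replicate 1 or 4, and those of mmu-miR-32-5p and mmu-miR-181b-5p without ethanol replicate 2 (edgeR adjusted p 0.0572 to 0.159).

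RNAs of blood, muscle and stromal cells were lower as well. Of red blood cell miRNAs 5 of 5 fell (5 adjusted over the list alone), with a median log2 fold change of -2.37, or -3.05 without control replicate 3 and -1.68 without control replicate 4. mmu-miR-451a fell from 377 ± 358 to 45.8 ± 24.1 CPM (-3.04 ± 0.75), and mmu-miR-486a-5p (-2.37 ± 0.64) and mmu-miR-486b-5p (-2.34 ± 0.61) fell with it. Of white blood cell miRNAs 3 of 5 fell (4 adjusted over the list alone), with a median of -1.72, or -2.44 without ethanol replicate 3. These were mmu-miR-150-5p (-2.60 ± 0.62), mmu-miR-155-5p (-1.72 ± 0.46) and mmu-miR-223-3p, which went from 22.3 ± 15.5 to 5.58 ± 2.42 CPM. Of muscle and stromal miRNAs 5 of 9 fell (7 adjusted over the list alone), with a median of -2.44, among them mmu-miR-133a-3p (-2.34 ± 0.61), mmu-miR-1a-3p (-2.44 ± 0.70), mmu-miR-199a-3p (-2.63 ± 0.75) and mmu-miR-199a-5p (-3.03 ± 0.87). Control replicate 2 had 8473 CPM of mmu-miR-199a-3p, against 879.8 to 1249 in the other controls. Without it the median of the list was -1.17, and the log2 fold changes of mmu-miR-199a-3p, mmu-miR-199a-5p and mmu-miR-1a-3p were -1.28, -1.004 and -1.56. Of 5 tested transcripts of blood and immune cells 2 fell (4 adjusted over the list alone), the alpha-globin genes Hba-a1 (-2.02 ± 0.49) and Hba-a2 (-2.01 ± 0.51), which are near-identical copies that can share reads. The median of that list was -1.78, or -2.67 without ethanol replicate 4 and -0.49 with no low-count filter, where 15 genes were tested. Compared with other miRNAs alone, the medians of the red cell, white cell and muscle lists were -0.86, -0.43 and -0.87, and none passed camera. All 4 lists passed camera over all features with the preset correlation (adjusted p = 0.000192, 0.000636, 0.000135 and 0.000317) and none when it was estimated (adjusted p = 0.210 with an estimated correlation for each). fry gave them 0.0470, 0.0314, 0.0763 and 0.0406, so the muscle list did not pass it. mmu-miR-122-5p, a liver miRNA, had a log2 fold change of -2.89 ± 0.94, or -1.76 without control replicate 2 and -4.08 without ethanol replicate 2. It did not pass over all features (edgeR adjusted p = 0.0609). As the only member of its list it got no adjustment over the list, and its unadjusted edgeR p was under 0.05. The calls named here ended without each control. Those of mmu-miR-451a, mmu-miR-486a-5p, mmu-miR-150-5p, mmu-miR-199a-3p and mmu-miR-199a-5p also ended without ethanol replicate 2, those of mmu-miR-486a-5p, mmu-miR-199a-3p and mmu-miR-199a-5p without ethanol replicate 1, those of mmu-miR-155-5p, mmu-miR-1a-3p, mmu-miR-199a-3p and mmu-miR-199a-5p without ethanol replicate 4, and that of mmu-miR-199a-5p without ethanol replicate 3 (edgeR adjusted p 0.0523 to 0.259).

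Exon fragments of genes of the epididymal epithelium, the tissue that sperm pass through as they mature, were higher in ethanol sperm. Of 26 genes in the list 8 had enough counts, and 7 of these rose (7 adjusted over the list alone), with a median log2 fold change of 3.83. Crisp1, a secreted protein that binds to sperm, rose from 477 ± 119 to 3399.6 ± 4064 CPM (2.83 ± 0.71), and Gpx3, a secreted glutathione peroxidase, from 38.7 ± 8.55 to 510.4 ± 736 CPM (3.72 ± 0.86). Spink8, of a protease inhibitor family, rose by 2.49 ± 0.63, and Rnase12, of the ribonuclease A family, from 1.51 ± 0.681 to 23.9 ± 35.05 CPM (edgeR adjusted p = 0.0287 to 0.0324 over these 4 genes); no gene of this list is in another list. In each of the 4 all ethanol libraries lay above every control library, and ethanol replicate 2 lay highest. Without that library the log2 fold changes of Crisp1, Gpx3, Spink8 and Rnase12 were 1.48, 1.83, 1.46 and 2.03, and the median of the list was 1.71. That median was 1.07 with only the 2 ethanol libraries whose sample code begins with POEM, and 2.30 with no low-count filter, where 26 genes were tested. Without each control their calls ended (edgeR adjusted p 0.0615 to 0.130). The list passed camera with the preset correlation with ethanol replicate 2 and without it (adjusted p = 0.000115 and 4.19e-05), but had an adjusted p = 0.210 with an estimated correlation and did not pass fry (0.0590). Gpx5, named after its value was seen, had 3.79 ± 4.65 and 9.95 ± 4.69 CPM and did not pass (edgeR adjusted p = 0.180). Of 6 miRNAs of epididymal and other epithelia 0 passed the edgeR test over all features (0 adjusted over the list alone), with a median of -0.46, a camera adjusted p of 0.570 and an adjusted p = 0.717 with an estimated correlation. mmu-miR-200a-3p and mmu-miR-200b-3p had log2 fold changes of -0.25 ± 0.56 and -0.77 ± 0.52, the former -1.07 without ethanol replicate 3. Compared with other miRNAs alone the median of this list was 0.84 (camera adjusted p = 0.0490 with the preset correlation; adjusted p = 0.646 with an estimated correlation).

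**Figure D2:**
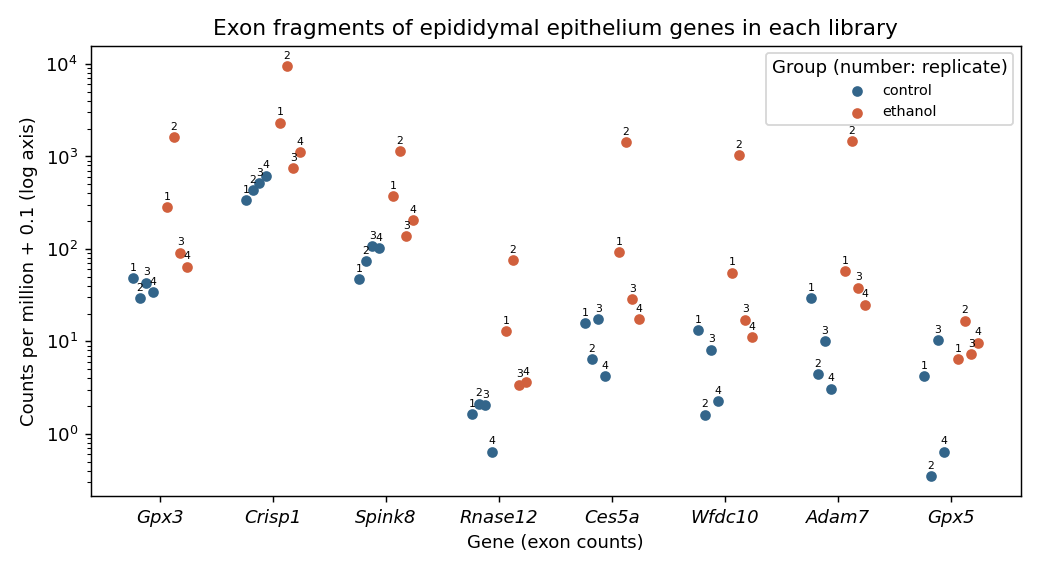
CPM plus 0.1 on a log axis (y axis) of exon fragments of the 8 tested epididymal epithelium genes (x axis) in each of 4 control and 4 ethanol libraries; numbers give the replicate. Ethanol replicate 2 lies highest for all 8 genes, and for Crisp1, Gpx3, Spink8 and Rnase12 the other ethanol libraries also lie above every control library.

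Exon fragments of nuclear genes of oxidative phosphorylation, the mitochondrial route of ATP production, were higher in ethanol sperm, as were those of the epididymis list. Of 66 tested 54 rose and 0 fell (60 rose and 1 fell, Ndufv2, adjusted over the list alone), with a median log2 fold change of 2.05 against 0.88 for all mRNA exons. The ATP synthase genes Atp5d and Atp5g2 rose by 2.80 ± 0.54 and 2.29 ± 0.47, the former from 2.94 ± 1.36 to 20.7 ± 15.8 CPM. The complex I gene Ndufc2 rose from 1.52 ± 0.421 to 12.5 ± 11.8 CPM and the complex IV gene Cox5b by 2.69 ± 0.56, all 4 with an edgeR adjusted p of 0.0287 and with 4 of 4 ethanol libraries above every control. Ethanol replicate 2 lay highest for each of the 4 genes, as it did for the epididymis genes. The list passed camera with the preset correlation (adjusted p = 2.72e-18), but had an adjusted p = 0.210 with an estimated correlation; fry gave 0.0470. Its median was 1.33 without ethanol replicate 2, and the calls of the 4 named genes ended without each control (edgeR adjusted p 0.0615 to 0.0949). Of the 13 protein-coding genes of the mitochondrial genome 0 passed the edgeR test over all features (0 adjusted over the list alone; 0 at an unadjusted p under 0.05), with a median of -0.41. As a set they had a camera adjusted p of 0.180 (adjusted p = 0.717 with an estimated correlation), which became 0.0450 without control replicate 1 (median -0.66) and 0.00333 without control replicate 2 (median -0.77). COX1 had 851 ± 297 and 476 ± 108 CPM, and COX2 279.7 ± 169 and 203 ± 15.4 CPM. The list of mitochondrial tRNAs and rRNAs held tRNA-Ser-TCA(m) and tRNA-Leu-TTA(m), taken as mitochondrial from the (m) in their names. What (m) stands for is not given in the sources used here, so a mitochondrial origin is uncertain. Their log2 fold changes were -0.83 ± 0.46 and -0.76 ± 0.40, and neither passed (edgeR adjusted p = 0.222 and 0.198, with 0 of 2 adjusted over the list alone).

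**Figure D3:**
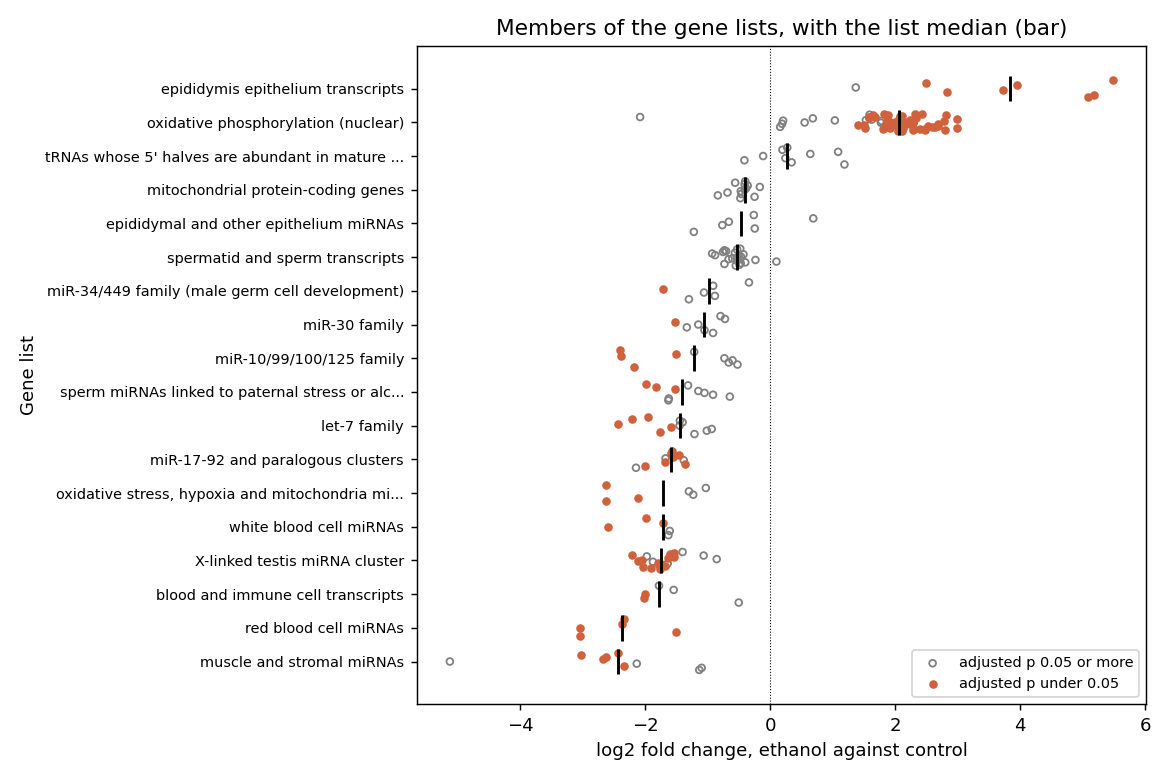
Log2 fold change in ethanol against control sperm (x axis) of each tested member of the gene lists (y axis); filled points passed an edgeR adjusted p of 0.05, open points did not, and bars are list medians. The nuclear oxidative phosphorylation and epididymis lists lie furthest to the right, with medians of 2.05 and 3.83.

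Of 22 tested transcripts of spermatids and sperm 0 passed the edgeR test (0 adjusted over the list alone), and 21 had a negative log2 fold change, with a median of -0.53. The set passed camera with the preset correlation (adjusted p = 0.000192), but had an adjusted p = 0.436 with an estimated correlation and did not pass fry (0.173). The mitochondrial capsule gene Smcp had 203 ± 18.1 and 107 ± 33.1 CPM (edgeR adjusted p = 0.125) and the outer dense fibre gene Odf1 had 136 ± 19.9 and 93.5 ± 37.8 CPM (edgeR adjusted p = 0.383). Without ethanol replicate 3 the median was -0.88, and with only the 2 ethanol libraries whose sample code begins with POEM the camera adjusted p was 0.139.

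Of 57 tRNA features 0 passed the edgeR test over all features and 0 over tRNA features alone. At an unadjusted p under 0.05 there were 2, tRNA-Asp-GAY and tRNA-Thr-ACY. DESeq2 called 1, tRNA-Asp-GAY, and limma-voom 0. Without ethanol replicate 3, 2 passed, tRNA-Asp-GAY upward (log2 fold change 1.25) and tRNA-Arg-CGA_ downward (-1.30); these 3 features were named after their values were seen. The tRNAs whose fragments are abundant in mature sperm had a median log2 fold change of 0.27 over 9 features, of which 0 passed (0 adjusted over the list alone), with a camera adjusted p of 0.638 and an adjusted p = 0.827 with an estimated correlation. The median was -0.38 without ethanol replicate 4, 0.51 without ethanol replicate 2 and 0.07 without control replicate 1 or 2. tRNA-Gly-GGY, a glycine tRNA, had 92035 ± 20942 and 85023 ± 49888 CPM (log2 fold change -0.11 ± 0.51, or 0.13 without ethanol replicate 2), and tRNA-Glu-GAG_, a glutamate tRNA, 95189 ± 15269 and 71453 ± 34976 CPM (-0.41 ± 0.46). Of 111 piRNA clusters 0 passed the edgeR test, with 2 at an unadjusted p under 0.05 (pi-Foxo3, named after its value was seen, and 1 cluster named by its chromosome band) and a median of -0.08. That median was 0.09, and that of noncoding exons 0.11, when libraries were scaled by their totals, a scaling that moved the median of all features from -0.01 to 0.24. No direction is therefore given for either class.

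Both Y RNAs, which bind the Ro protein, were higher in ethanol sperm without passing over all features, and 2 of 2 passed adjusted over the list alone. When libraries were scaled by their totals, 1 of the 2 passed over all features, and their median log2 fold change was 1.56. HY3 had 187 ± 19.3 and 419 ± 131 CPM (log2 fold change 1.17 ± 0.41, edgeR adjusted p = 0.0700), above every control in 4 of 4 ethanol libraries, and passed without ethanol replicate 3 (1.22). HY1 had 262 ± 51.3 and 588 ± 419 CPM (1.17 ± 0.51, edgeR adjusted p = 0.125), above every control in 3 of 4 ethanol libraries, with 1193 CPM in ethanol replicate 2. Without that library its log2 fold change was 0.50. The snoRNA Snord85 fell from 1249 ± 190.1 to 296 ± 179 CPM (-2.08 ± 0.51, edgeR adjusted p = 0.0287), a call that ended without each control (edgeR adjusted p 0.0615 to 0.0949), whereas Snord2 did not pass (-0.78 ± 0.42, edgeR adjusted p = 0.204). Of 11 features annotated as snRNA 2 fell, U13 and U17 (log2 fold changes -1.38 and -1.53, named after their values were seen), which act in ribosomal RNA processing. Both calls ended without each control and without ethanol replicate 4, and that of U17 also without ethanol replicate 1 (edgeR adjusted p 0.0674 to 0.138). Both also ended when libraries were scaled by their totals (edgeR adjusted p 0.0877 and 0.0566). The spliceosomal U1 and U4 did not pass (0.94 ± 0.65 and -0.76 ± 0.44, edgeR adjusted p = 0.322 and 0.235), although U4 did without ethanol replicate 3 (-1.21). U1 had 11667 CPM in ethanol replicate 2 and 1313 to 1812 in the other ethanol libraries, and its log2 fold change was -0.48 without that library, so no direction is given. The small cytoplasmic 4.5SRNA had 3452 ± 1534 and 1634 ± 747 CPM (edgeR adjusted p = 0.141) and passed without ethanol replicate 3 (-1.50). 7SLRNA, of the signal recognition particle, had 3762 ± 715 and 4747 ± 2737 CPM (edgeR adjusted p = 0.640), with 8771 CPM in ethanol replicate 2. Its log2 fold change was -0.20 without that library, so no direction is given for it either. These RNAs have many near-identical genomic copies, among which reads cannot be placed with certainty.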

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

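The tests of ethanol replicate 2 on the epididymis list, of composition, of library depth and of epididymal cells on the oxidative phosphorylation list were chosen after the result was seen; the others were written down first. Of 238 groups of 4 libraries, 25 had a library far from the other 3. The library was control replicate 2 in 10 of them and ethanol replicate 2 in 9. Chance gives about 1 in 20 groups only for independent, normally distributed values. CPM and shares were not shown to be normally distributed, and many of these features moved together, so that rate does not apply here.

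Control replicate 2 lay far from the other controls in the miRNA share, with 28.0%, and in 9 miRNAs. It had 214 CPM of mmu-let-7e-5p, 923 of mmu-let-7i-5p, 25.3 of mmu-miR-98-5p, 45.3 of mmu-miR-223-3p, 8473 of mmu-miR-199a-3p, 614 of mmu-miR-199a-5p, 78.9 of mmu-miR-99b-5p and 37.7 of mmu-miR-100-5p, each above the other controls. mmu-let-7a-5p was listed at 0 there. Ethanol replicate 2 lay above the other ethanol libraries in the shares of mRNA exons (30.4%), snRNA (2.63%) and srpRNA (1.27%). It also lay above them in CPM of Gpx3 (1604), Rnase12 (76.1), Ndufc2 (30.03), Atp5g2 (22.005), U1 (11667) and mmu-miR-122-5p (4.52). Ethanol replicate 3 lay above its group for mmu-miR-17-3p (2.95 CPM), mmu-miR-17-5p (6.63 CPM) and mmu-miR-200a-3p (1896 CPM). Control replicate 4 lay above its group for the hairpin of mmu-mir-196a-1 (1.63 CPM) and tRNA-Glu-GAG_ (117980.0 CPM), and control replicate 3 lay below its group for 5S rRNA (22.5 CPM).

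Exon fragments of epididymal epithelium genes were higher in ethanol sperm, with a median log2 fold change of 3.83. Ethanol replicate 2 was not the only library with higher values, since the median without it was 1.71. The mean log2 CPM of the list was 6.57, 5.29 and 5.19 in ethanol replicates 1, 3 and 4 and 3.33 to 4.57 in the controls. Without ethanol replicate 2 the list passed camera with the preset correlation but not with an estimated one (camera adjusted p = 0.157, and 0.210 with all libraries). The median was 1.07 with only the ethanol libraries whose sample code begins with POEM. How much of the difference rests on ethanol replicate 2 therefore stays open. With all libraries the 8 tested genes rose more than most mRNA exons, with a lower quartile of 2.75 against an upper quartile of 1.45 for all mRNA exons. That comparison covers only genes with enough counts and was not repeated without ethanol replicate 2. A general rise of mRNA exons is therefore not excluded. Carry-over of epididymal epithelial cells with their small RNAs may contribute: among miRNAs alone the epithelium list had a median of 0.84, more than the spread of its members (quartiles 0.73 and 0.98). That spread leaves out the standard errors of the members, and camera gave the list an adjusted p = 0.646 with an estimated correlation. One of its members, mmu-miR-141-3p, was listed at 0 in 4 libraries. In the fit over all features the same list had a median of -0.46 and did not pass. An effect of ethanol on what sperm take up in the epididymis stays open and was not tested.

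The miRNA share was lower in every ethanol than in every control library. Miscounted zeros do not account for it, since the gap between the groups was 5.14 percentage points with the miRNAs concerned left out. The listed blood, muscle and stromal miRNAs alone do not either, with a gap of 4.50 percentage points without them. Other miRNAs that such cells may carry were not left out, so a contribution of these cells stays open. Library depth stays open: the shallower library had the higher share in 5 of 6 pairs of controls and in 0 of 6 pairs of ethanol libraries, and 3 of 4 ethanol libraries were deeper than every control, but the other, ethanol replicate 2, was shallower than every control and had the lowest share of all, 6.47%, which speaks against depth in that 1 library. The ratio of miRNA to 7 of 8 other classes was lower in every ethanol than in every control library. The exception was snRNA, where the mean ratio went from 19.4 to 10.9. More counts in 1 other class alone would leave the ratios to the remaining classes unchanged. However, the classes are not separate. An abundant feature each of the piRNA cluster, intron, noncoding exon and antisense transposon classes had counts in nearly the same order across libraries. The 7 ratios are therefore not separate tests, and more counts in some other classes (composition) stays open. Shares do not separate a fall of miRNA from a joint rise of nearly all other classes, and an effect of ethanol on sperm miRNA also stays open and was not tested.

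Exon fragments of nuclear oxidative phosphorylation genes rose, with a median of 2.05. Ethanol replicate 2 was not the only library with higher values, since the median without it was 1.33. The mean log2 CPM of the list was 3.04, 2.66 and 3.13 in ethanol replicates 1, 3 and 4 and 1.40 to 2.05 in the controls. Without ethanol replicate 2 the list passed camera with the preset correlation but not with an estimated one (camera adjusted p = 0.157, and 0.210 with all libraries). How much of the rise rests on ethanol replicate 2 therefore stays open. The rise may be shared with other abundant housekeeping mRNAs, as ribosomal protein exons had a median of 2.14, inside the quartiles of the oxidative phosphorylation genes (1.65 to 2.29). Carry-over of epididymal epithelial cells stays open: the epididymis list rose in the same libraries while 21 of 22 spermatid and sperm transcripts were lower, but within the groups both lists put only 6 of 12 pairs of libraries in the same order. The values thus show no rise particular to mitochondrial genes, and an effect of ethanol on such mRNAs in general stays open and was not tested.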

How the results depend on the processing

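The largest row per name, the removal of miRNAs with a doubtful 0 and the removal of both replicates numbered 2 were chosen after seeing the data. The count of 1841 features was 1200 with DESeq2 size factors, 3144 with the DESeq2 Wald test, 8 with limma-voom, 3451 with no low-count filter and 574 with the largest row per name, where 6934 features were tested. It was 3320 with the pair of ethanol libraries whose sample codes begin with POM and 816 with the pair whose codes begin with POEM. Without 1 library it ranged from 3 to 3575. The count of 90 miRNAs was 1 with limma-voom, 161 with no low-count filter, 155 with the POM pair, 35 with the POEM pair and 1 with miRNAs alone in the fit, and 1 to 158 without 1 library. The count of 0 tRNA features was 1 with the DESeq2 Wald test, 1 with the POM pair and 0 to 2 without 1 library. Of the gene lists 14 of 18 tested passed, 0 with an estimated inter-gene correlation and 13 to 15 without 1 library; 9 passed fry, and 0 to 11 did so without 1 library. For RNA classes the exact permutation p cannot fall under 0.0286, or 0.125 with sign flips, and at least 10 of 16 classes at 0.0286 would be needed for any to pass, so the 0 classes past the threshold say nothing about stability. The causes of these differences were not tested, apart from the smaller number of features or libraries where an alternative leaves some out.

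The values did not show that the replicate numbers pair the samples: correlations of deviations from the group means were 0.341, 0.209, -0.127 and -0.0201 for numbers 1 to 4. So few values cannot rule a pairing out. With the replicate block 3298 features and 126 miRNAs passed, and 14 lists with the preset correlation, but 0 with an estimated one and 0 in fry, against 9 in fry without the block.

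The 70 named features past the threshold had 1429 values in alternatives, of which 1428 kept their sign, 960 were also past the threshold and 468 were not. The exception was mmu-miR-125b-5p, at 0.0388 with miRNAs alone in the fit. That fit scales miRNAs against each other, which moved their median log2 fold change from -1.52 to -0.10. Kept signs were likely in advance, since the alternatives used the same libraries in which the 70 features were called. Of 644 values of the 32 other named features 13 passed the threshold and 56 had the opposite sign without passing.

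Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many features as the real 1841, the real split itself. The highest of the others gave 1. Every other split mixes the groups, which widens the spread within each side, so low counts were likely there in advance. The real split thus stood alone, but this does not exclude chance. The same holds for miRNAs, with 90 in the real split, 1 split as large and 1 at most in the others. All 35 splits gave 0 tRNA features, which is no test, since any count reaches a real count of 0. For gene lists 4 of 35 splits gave 14 or more, the highest other 15, so chance cannot be excluded. At this depth and spread the simulated 2-fold changes were recovered in 1% of cases, in a simulation where few features changed.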

Other observations

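Features in this part were chosen after their values were seen, apart from ribosomal protein exons, whose test was written down first, and Snord32a, named by the rule. Ribosomal protein genes, which encode the protein part of the ribosome, gave exon fragments that rose in 75 of 78 cases, with a median log2 fold change of 2.14. Without each control 0 of them passed the edgeR test (median 1.87 to 2.05), and without ethanol replicate 2 the median was 1.29, with 67 of 78 past it. snoRNAs that lie in introns of the ribosomal protein gene Rpl13a went the other way: Snord32a, Snord33, Snord34 and Snord35a fell, with log2 fold changes of -1.78 ± 0.37, -1.62 ± 0.41, -1.36 ± 0.39 and -1.32 ± 0.36. Snord95 fell from 304 ± 61.2 to 105 ± 40.7 CPM. Among noncoding exons Tug1, a long noncoding RNA, rose from 18.1 ± 5.26 to 414 ± 684 CPM, with 1438 CPM in ethanol replicate 2 and 42.95 to 97.1 in the other ethanol libraries; its log2 fold change went from 4.51 to 1.93 without ethanol replicate 2. Rmrp, the RNA of a ribonuclease that processes ribosomal RNA, fell from 263 ± 50.3 to 85.6 ± 23.9 CPM. The calls on single features in this paragraph ended without each control, those of Rmrp, Snord33, Snord34, Snord35a and Snord95 also without ethanol replicate 4, and those of Snord34 and Snord35a without ethanol replicate 1 (edgeR adjusted p 0.0506 to 0.107). Those of Snord33, Snord34 and Snord35a also ended when libraries were scaled by their totals (edgeR adjusted p 0.0549, 0.0701 and 0.0913).

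Sense-strand counts of the murine leukemia virus elements MuLV-int and RLTR4_Mm and of the retroviral repeat RLTR3_Mm rose, the 3 sense transposon features that did so. MuLV-int went from 364 ± 165 to 1658 ± 804 CPM (2.19 ± 0.51, edgeR adjusted p = 0.0287), and RLTR4_Mm and RLTR3_Mm had log2 fold changes of 1.66 ± 0.47 and 1.67 ± 0.45. With adjustment over sense transposons alone none of the 3 passed (edgeR adjusted p of MuLV-int 0.108, the lowest). Antisense counts of MMERGLN-int rose from 69.6 ± 17.7 to 391 ± 520.2 CPM, with 1169.8 CPM in ethanol replicate 2, and its call ended without that library (log2 fold change 0.86, edgeR adjusted p 0.111). All 4 calls ended without each control, and those of the 3 sense features also without ethanol replicate 4 (edgeR adjusted p 0.0504 to 0.168). Copies of these elements are near-identical, so their reads cannot be assigned to single loci.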
